A study of Mus musculus with 15 samples.

How the data were processed

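Total RNA from mammary tumours of female MMTV-PyMT mice was hybridised to 15 Agilent 1-colour arrays, each labelled with Cy3. Per the labels' protocols, treatment started at 7 weeks of age, RNA was extracted on silica columns, and 0.5 ug of RNA per sample was labelled with a low-input kit. The samples were grouped by their titles into T0 (before any treatment, n = 4), vehicle (n = 3), B20 (n = 4) and nintedanib (n = 4). T0 replicate 4 carries 2 treatment labels, before any treatment and vehicle, and was kept in T0 as its title gives it. The labels do not state that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be in part technical.

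Per the file headers, the arrays (design 028005, 62976 spots, grid annotated on mm9) were scanned on a G2505C scanner and read with Feature Extraction 10.7.3.1, which subtracted the background and detrended each array. The values used here are the spot intensity (processed signal) that the authors deposited for each array, which was not normalised between arrays. The flags for spots well above background, saturated spots and outlier spots are other values taken per the file headers as 0 or 1. The authors' table of the whole series holds log2 values whose making is not given in the sources used here. It was set against each array's own signals: normexp background correction with an offset of 50 followed by quantile normalisation gave nearly the same values (median r over arrays 0.999985, highest median absolute difference 0.0242 log2). Its column medians lay between 6.616 and 6.627, no gene was centred, and a higher value stood for a brighter spot.

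Control spots and outlier spots were left out, leaving 59305 spots of 55681 probes per array, and spots of 1 probe were averaged. In 82 cases every spot of a probe was an outlier on an array and the probe's mean over its other arrays took its place. No spot was saturated. Each array's log2 processed signal was scaled by subtracting its 75th percentile, with no constant added before the logarithm. Probes well above background on at least 3 of the 15 arrays were kept. Probes were named by matching the array's transcript identifiers to a table of mouse RefSeq genes (assembly GRCm38.p6, used for names only). This gave 26056 probes a symbol, 19752 symbols in all, and left 29625 probes unnamed, which keep the identifier of the array design. For each gene the probe with the highest mean signal was used, so 28074 genes or unnamed transcripts were tested, 16141 of them with a symbol. No genome was used, so no positions are given.

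The depth of an array is its signal over background. Medians of raw signal were 55 to 102 against a median local background of 19 to 26, and 53.5% to 68.1% of probes were well above background on 14 of the arrays, against 84.2% on T0 replicate 3. The number of arrays limits the precision: the median SE of a difference was 0.29 log2 for 4 against 3 arrays and 0.268 log2 for 4 against 4. Where a probe was not well above background on any array of a group, the fold is given as at least a value. For this, the bright group's mean was set against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. It is a bound in the processed signal only, equal or close to the fitted fold here, and another background correction can give less.

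Tests were made in R 4.3.3 with limma 3.58.1. One linear model (lmFit, eBayes) with 4 group means was fitted to the 15 arrays. Contrasts were nintedanib vs vehicle, B20 vs vehicle, nintedanib vs B20, vehicle vs T0, nintedanib vs T0 and B20 vs T0. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Errors of fold changes are the standard errors of the fit, and errors of group means are SDs. The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made after seeing them.

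The 33 gene lists were glycolysis, hypoxia response, pentose phosphate, TCA cycle, OXPHOS subunits, mitochondrial biogenesis regulators, mitochondrial ribosome, fatty acid oxidation, ketone body metabolism, lipid synthesis, drug targets and ligands, cell cycle, interferon response, ER and amino acid stress, EMT and TGF-beta response, immediate early genes, ribosomal proteins, endothelium, angiogenic endothelium, lymphatic endothelium, pericytes and smooth muscle, fibroblasts and matrix, macrophages, neutrophils, T and NK cells, B and plasma cells, adipocytes, luminal epithelium, milk genes, basal epithelium, skeletal muscle, skin and erythroid cells. Each list with at least 5 measured members was tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists of a comparison, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance 1 way. Members were also counted with p adjusted over the list alone. An exact permutation test of the list's mean signal per array, two-sided and adjusted over the 33 lists of each of the 6 comparisons, was chosen after seeing the data. The smallest p it can give is 0.0286 with 4 against 3 or with 4 against 4 arrays.

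Genes were named by this rule for the first 4 comparisons. The 6 largest rises and 6 largest falls came from genes with an adjusted p under 0.05 whose groups did not overlap, leaving out predicted and unnamed genes. Where fewer passed, the places went to the genes of lowest p, which are then said not to have passed. Up to 4 members of lowest p came from each called list and, in any case, from glycolysis, hypoxia response, OXPHOS subunits, fatty acid oxidation, endothelium, angiogenic endothelium and cell cycle. Vegfa, Kdr, Flt1, Pdgfrb, Slc2a1, Hk2, Ldha, Pdk1 and Car9 were always included. Not every gene the rule took is named in the text. For nintedanib vs T0 and B20 vs T0 only counts and list calls were taken.

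The arrays lie on 4 slides scanned on 2 days. Slide 1 holds B20 replicates 1 to 3, nintedanib replicates 1 to 3 and vehicle replicates 1 and 2, and slide 4 holds B20 replicate 4, nintedanib replicate 4 and vehicle replicate 3. T0 replicates 1 and 2 lie on slide 2, and T0 replicates 3 and 4 on slide 3. All T0 arrays were scanned on the other day, so scan day and T0 against end of treatment cannot be told apart. The slide was fitted as a fixed block over the 11 end-of-treatment arrays, as a random block over the 15 arrays (consensus correlation 0.131), and differences were taken within slides 1 and 4.

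Other settings tried were normexp background correction, quantile normalisation, scaling to the median, the authors' values, no filter on dim probes and a filter on 15 of 15 arrays, the mean of a gene's probes, each probe on its own, only the arrays of the compared groups, an intensity trend with a robust prior, array weights, the slide and the replicate number as blocks, an adjusted p under 0.10, a 2-fold minimum, and each array left out in turn. Others were added after seeing the data.

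The procedure was tested on simulated data in which 50 genes each were shifted by 0.5, 1, 2 and 3 log2 among 28074. For nintedanib vs vehicle it recovered 2%, 24%, 72% and 84% of them, and for B20 vs vehicle 0%, 30%, 74% and 82%. For nintedanib vs B20 it recovered 0%, 20%, 76% and 80%, and for vehicle vs T0 0%, 20%, 76% and 86%. For nintedanib vs T0 it recovered 6%, 26%, 74% and 90%, and for B20 vs T0 6%, 32%, 86% and 88%. Unchanged genes called numbered 7, 7, 3, 1, 6 and 0 in the same order of comparisons. The 2 lists shifted by 0.5 log2 were called each time, with 1 other list for vehicle vs T0. Mixed-group splits of the real arrays called a median of 10 to 13 lists, so the simulation cannot vouch for list calls. Nor can it for power where the real fits called 0 genes, against 93 to 102 simulated. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.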

Results

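Mammary tumours of MMTV-PyMT mice, in which a viral oncogene under a mammary promoter gives rise to carcinomas, were profiled before any treatment (T0, n = 4) and at the end of treatment with vehicle (n = 3), B20 (n = 4) or nintedanib (n = 4). B20 is an antibody that binds VEGF, the main growth factor of blood vessels, and was injected at 5 mg per kg, 2 times per week. Nintedanib inhibits the receptor kinases of VEGF, FGF and PDGF and was given by mouth at 85 mg per kg per day. The series concerns tumour mitochondrial metabolism under antiangiogenic drugs, so the lists of genes covered energy metabolism, the vasculature and the other cell types that a mammary tumour dissection can hold. Gene levels are log2 spot signals relative to the 75th percentile of their array, and differences are in log2 with the SE of the fit.

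The first comparison asked what nintedanib changed in the tumours relative to vehicle. Interferon response genes, which encode antiviral and antigen-presentation proteins, rose with nintedanib: the mean level of the list was 1.90 ± 0.35 (SD, n = 4) against 0.52 ± 0.35 (SD, n = 3) with vehicle, a 2.6-fold difference. Of the 30 members measured, 29 were higher, 26 rose when p was adjusted over the list alone and none passed over all genes (adjusted p = 0.0604 for the list with an estimated correlation). Cell cycle genes, which drive DNA replication and mitosis, fell, from a mean level of 1.78 ± 0.08 (SD, n = 3) to 1.36 ± 0.16 (SD, n = 4), with 39 of 40 members lower and none passing (adjusted p = 0.781 with an estimated correlation). Marker genes of adipocytes were higher in the nintedanib tumours by a median of 1.96, those of skeletal muscle by 0.91 and those of erythroid cells by 0.93 (adjusted p = 0.781, 0.825 and 0.781 with an estimated correlation).

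Among the interferon response genes, Oas2, an antiviral synthetase that senses double-stranded RNA, differed by 2.87 ± 0.54 (3.07 ± 0.94, SD, n = 4, against 0.19 ± 0.83, SD, n = 3). It differed by 3.21 within the slide of 8 arrays and 2.10 within the slide of 3. Oasl2, a relative of Oas2, differed by 2.62 ± 0.49, Ifit3b by 2.42 ± 0.44, and Irf7, a transcription factor of the interferon response, by 2.30 ± 0.44. Gbp2b, which was well above background on 1 of 3 vehicle arrays, differed by 2.26 ± 0.41 (0.39 with normexp and 0.45 with the authors' values). Trim30a, Xaf1, Igtp and Iigp1, all induced by interferons, differed by 1.82 ± 0.30, 1.69 ± 0.30, 1.62 ± 0.29 and 1.25 ± 0.21. None of these 9 genes passed over all genes (adjusted p = 0.27 for each). The list was called with camera (adjusted p = 2e-42), and the exact permutation test of its mean gave p = 0.0286, the smallest possible (adjusted p = 0.471).

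Within the cell cycle list, Kif11, a mitotic motor, differed by -0.82 ± 0.26, Ccne1, a cyclin of S phase entry, by -0.67 ± 0.21 (-0.38 with the mean of its probes), and the replication helicase subunits Mcm2 and Mcm4 by -0.60 ± 0.24 and -0.57 ± 0.21. None of them passed (adjusted p = 0.803 to 0.961). The list's median was -0.48 (camera adjusted p = 4.14e-13; exact permutation p = 0.0286, adjusted p = 0.471). Outside the lists the lowest p among lower genes belonged to Frmd4a (-0.85 ± 0.18, adjusted p = 0.33).

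Of the energy metabolism lists, glycolysis rose by a median of 0.17 (19 of 23 higher; adjusted p = 0.825 with an estimated correlation for this list and the next 3). OXPHOS subunits, which build the respiratory chain, fell by 0.15 (66 of 76 lower) and mitochondrial ribosome genes fell by 0.14 (61 of 74 lower). Ribosomal proteins of the cytosol also fell by 0.17 (71 of 76 lower). No member of these lists passed, alone or over all genes, and adjusted p was 0.0224, 0.00654, 0.0113 and 0.000183 with camera. The same arrays carried the higher adipocyte and muscle markers given above. The OXPHOS call ended without nintedanib replicate 1, nintedanib replicate 2 or vehicle replicate 2 (adjusted p = 0.54, 0.143 and 0.334), with normexp (0.234), quantile normalisation (0.125) and the authors' values (0.224). That of the mitochondrial ribosome ended without nintedanib replicates 1 or 2 or vehicle replicates 1 or 2 (adjusted p = 0.787, 0.0945, 0.0523 and 0.74), with normexp (0.223) and with median scaling (0.055). Ribosomal proteins lost their call without nintedanib replicate 2 (0.432), with quantile normalisation (0.74) and with the authors' values (0.697). Glycolysis lost its call without nintedanib replicates 1 or 2 or vehicle replicate 2 (0.346, 0.0815 and 0.41), with median scaling (0.0645) and on the slide with 8 arrays alone (0.0509). Without nintedanib replicate 3 the 4 medians were 0.31, -0.25, -0.24 and -0.26, and without vehicle replicate 3 those of the mitochondrial ribosome and ribosomal proteins were -0.22 and -0.11.

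Of the immune markers called higher, macrophage genes had a median of 0.18 (16 of 18 higher, adjusted p = 0.0256), T and NK cell genes 0.16 (13 of 17 higher, adjusted p = 0.0184) and B and plasma cell genes 0.21 (7 of 10 higher, adjusted p = 0.0346). With an estimated correlation adjusted p was 0.825, 0.781 and 0.781. Adjusted over the list alone, 2 B and plasma cell genes rose, Cd79b, a part of the B cell receptor (1.13 ± 0.36), and Pou2af1, a B cell co-activator (0.99 ± 0.30). With the authors' values they differed by 0.54 and 0.60. The macrophage call ended without nintedanib replicates 2 or 3 or vehicle replicates 1 or 3 (adjusted p = 0.0744, 0.192, 0.442 and 0.0628), with the slide as a block (0.0522), median scaling (0.0817), array weights (0.143) and on the slide with 8 arrays alone (0.148). The list's median was 0.28 and 0.30 without nintedanib replicate 1 or vehicle replicate 2. The T and NK cell call ended without nintedanib replicate 4, where the median was -0.02 (adjusted p = 0.174), without vehicle replicate 1 (0.0523), with the authors' values (0.224) and on the slide with 8 arrays alone (-0.02, 0.489). Without nintedanib replicates 1, 2 or 3 the median was 0.36, 0.37 and 0.26. The B and plasma cell call ended without nintedanib replicates 3 or 4 or vehicle replicates 1 or 2 (0.139, 0.0641, 0.156 and 0.0558), with quantile normalisation (0.0999), the authors' values (0.0838), array weights (0.0839), only the arrays of the 2 groups (0.0527) or of the end of treatment (0.0646), and on the slide with 8 arrays alone (0.148). With normexp neither lymphocyte list was called (adjusted p = 0.103 and 0.223), and the B and plasma cell median was -0.03.

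Adipocyte markers (15 of 16 higher, camera adjusted p = 2.06e-09) included the fat hormones Retn (3.09 ± 0.99, adjusted p = 0.853) and Adipoq (2.48 ± 0.98, adjusted p = 0.961; 1.41 without vehicle replicate 1). Skeletal muscle markers (17 of 18 higher) had an adjusted p of 0.0346, and erythroid markers (6 of 6 higher), among them the haemoglobin gene Hba-a1 (1.22 ± 0.89), 0.00687. The muscle call ended without nintedanib replicates 2 or 3, T0 replicate 3 or vehicle replicates 1 or 2 (adjusted p = 0.0528 to 0.498), with the slide as a block (0.0939) and with the authors' values (0.0729). Its median was 1.49 and 1.83 without nintedanib replicate 4 or vehicle replicate 3, and that of adipocytes 1.18 without vehicle replicate 1.

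The endothelial lists did not pass: endothelium had a median of -0.14 (adjusted p = 0.465) and angiogenic endothelium 0.01 with a mean of -0.09 (adjusted p = 0.962). Esm1, a proteoglycan of endothelial tip cells, differed by -1.78 ± 0.64 (adjusted p = 0.915). The hypoxia response had a median of 0.21 (adjusted p = 0.0903). Of the genes chosen for their role in angiogenesis and glycolysis, Vegfa differed by 0.71 ± 0.47 (0.37 and 0.39 without nintedanib replicate 1 or vehicle replicate 2), its receptors Kdr and Flt1 by -0.21 ± 0.27 and -0.13 ± 0.44 and the PDGF receptor Pdgfrb by -0.17 ± 0.26. The glucose transporter Slc2a1 differed by 0.05 ± 0.26, Hk2 by 0.17 ± 0.56, Ldha by 0.02 ± 0.18, Pdk1 by 0.06 ± 0.19 and the hypoxia-induced carbonic anhydrase Car9 by 0.29 ± 0.42 (adjusted p = 0.999 for each). Medians of the other lists, none called, were -0.10 for pentose phosphate, -0.07 for the TCA cycle, -0.02 for mitochondrial biogenesis regulators, -0.13 for fatty acid oxidation, -0.09 for ketone body metabolism, 0.17 for lipid synthesis and 0.11 for drug targets and ligands. They were -0.07 for ER and amino acid stress, -0.06 for EMT and TGF-beta response, 0.11 for immediate early genes, 0.33 for lymphatic endothelium, 0.10 for pericytes and smooth muscle, -0.13 for fibroblasts and matrix and 0.23 for neutrophils. They were 0.01 for luminal epithelium, -0.08 for milk genes, -0.17 for basal epithelium and 0.22 for skin.

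Over all genes limma called 0 of 28074 (lowest adjusted p = 0.20), and 1387 had an unadjusted p under 0.05, against 1404 by chance. The groups did not overlap for 7.38% of genes, against 5.71% by chance. With array weights limma called 2, Trim30a (1.83, adjusted p = 0.0321) and an unnamed transcript, and without vehicle replicate 2 it called 1, Ppp4r4 (2.37, adjusted p = 0.0175), which was singled out after its value was seen. Camera called 12 of the 33 lists (8 higher, 4 lower), the estimated correlation 0 and fry 1, the interferon response (adjusted p = 0.020). Without nintedanib replicate 2 or vehicle replicate 1 camera called 7. Medians with the slide as a block were 1.57 for the interferon response, -0.47 for the cell cycle, 2.02 for adipocytes, 0.83 for muscle and 0.90 for erythroid cells. They were 0.18 for glycolysis, -0.15 for OXPHOS subunits, -0.15 for the mitochondrial ribosome, -0.16 for ribosomal proteins, 0.18 for macrophages, 0.19 for T and NK cells and 0.24 for B and plasma cells. Within the slide of 8 arrays and the slide of 3 arrays, list means differed by 1.39 and 1.35 for the interferon response, -0.52 and -0.17 for the cell cycle, 1.64 and 2.43 for adipocytes, 2.27 and -2.33 for muscle, and 0.78 and 1.24 for erythroid cells. They differed by 0.19 and 0.16 for glycolysis, -0.21 and 0.08 for OXPHOS subunits, -0.23 and 0.15 for the mitochondrial ribosome and -0.13 and -0.11 for ribosomal proteins. For macrophages, T and NK cells, and B and plasma cells they differed by 0.15 and 0.34, 0.12 and 0.83, and 0.22 and 0.48.

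**Figure D1:**
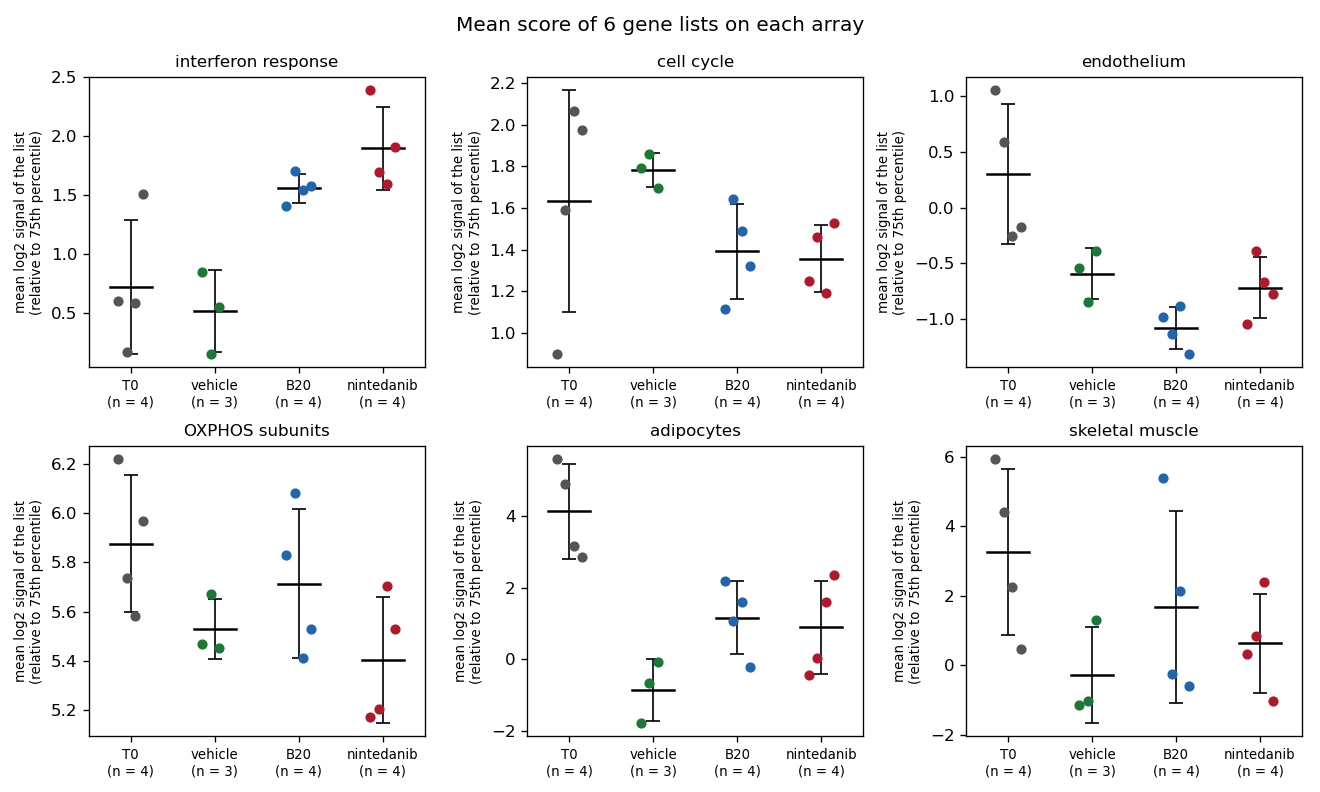
Mean log2 signal, relative to the 75th percentile of the array, of 6 gene lists in T0, vehicle, B20 and nintedanib tumours, with 1 point per array, bars at the group mean and error bars of 1 SD. For the interferon response the nintedanib mean is 1.90 and the B20 mean 1.56 against 0.52 with vehicle, and for adipocytes the T0 mean is 4.14 against -0.85 with vehicle.

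The comparison of B20 with vehicle asked the same of the antibody. Interferon response genes again rose, to a mean level of 1.56 ± 0.12 (SD, n = 4) from 0.52 ± 0.35 (SD, n = 3), a 2.06-fold difference, with 29 of 30 members higher and 18 rising when adjusted over the list alone. No gene passed over all genes, and the list had adjusted p = 0.216 with an estimated correlation. Cell cycle genes fell to 1.39 ± 0.23 (SD, n = 4), with 39 of 40 members lower (adjusted p = 0.482 with an estimated correlation; exact permutation p = 0.0571). Endothelial markers, which label the lining of blood vessels, fell from -0.59 ± 0.23 (SD, n = 3) to -1.08 ± 0.19 (SD, n = 4), with 27 of 28 members lower (adjusted p = 0.451 with an estimated correlation). Neutrophil markers rose by a median of 0.90 (0.29 without B20 replicate 2, 0.33 with normexp and 0.17 with the authors' values), and adipocyte and skeletal muscle markers were higher by medians of 2.07 and 2.08 (adjusted p = 0.451, 0.451 and 0.625 with an estimated correlation).

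Ubd, an interferon-induced ubiquitin-like protein, was not well above background on any vehicle array and at least 4.4-fold higher with B20 in the processed signal (adjusted p = 0.282), but differed by only 0.46 in log2 with normexp and 0.27 with the authors' values. Iigp1 differed by 1.24 ± 0.21 (adjusted p = 0.359), Xaf1 by 1.55 ± 0.30 (adjusted p = 0.567), Ifit3b by 2.14 ± 0.44 and Gbp2b by 1.97 ± 0.41 (adjusted p = 0.9 for both; Gbp2b 0.53 and 0.36 with those settings). Ifit3, Oas1a and Gbp3 differed by 1.93 ± 0.45, 1.82 ± 0.43 and 1.24 ± 0.30. None of these genes passed. The interferon list was called with camera (adjusted p = 1.18e-28), and the exact permutation test of its mean gave p = 0.0286 (adjusted p = 0.236).

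Of the endothelial genes, Tie1, a receptor kinase of vessels, stood at -3.17 ± 0.46 (SD, n = 4) with B20 and -2.07 ± 0.39 (SD, n = 3) with vehicle, a difference of -1.11 ± 0.36 (-0.86 within the slide of 8 arrays and -1.83 within the slide of 3). Sox18, a transcription factor of vessel development, differed by -1.04 ± 0.41 and the TGF-beta co-receptor Eng by -0.81 ± 0.31, none of which passed (adjusted p = 0.999 for each). With normexp Tie1 and Sox18 differed by -0.55 and -0.64. Among angiogenic endothelium genes, which had a median of -0.22 (10 of 14 lower), only Esm1 fell when adjusted over the list alone, by 2.55 ± 0.64 in log2 (-2.81 ± 1.05, SD, n = 4, against -0.26 ± 0.78, SD, n = 3; adjusted p = 0.999 over all genes). Within the 2 slides it differed by -2.49 and -2.45, and with normexp by -1.70. Adjusted p with camera was 1.44e-11 for endothelium and 0.0131 for angiogenic endothelium, and 0.451 for both with an estimated correlation. The exact permutation test of the endothelium mean gave p = 0.0286 (adjusted p = 0.236). The angiogenic call ended without vehicle replicates 1 or 3 (adjusted p = 0.251 and 0.163), with array weights (0.208), the authors' values (0.0772) and on the slide with 8 arrays alone (0.171), and the median was -0.33 without vehicle replicate 2. Fibroblast and matrix genes fell by a median of 0.27 (17 of 21 lower, adjusted p = 2.81e-05; adjusted p = 0.578 with an estimated correlation), and by 0.51 without vehicle replicate 2. That call ended without vehicle replicate 3 (adjusted p = 0.22), with array weights (0.207) and on the slide with 8 arrays alone (0.866).

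Neutrophil genes (9 of 10 higher, adjusted p = 0.000231) included the cytokine Il1b, which rose by 1.80 ± 0.42 when adjusted over the list alone, and S100a8, a calcium-binding protein of neutrophils, at 0.97 ± 0.40. The exact permutation test of the list mean gave p = 0.0286 (adjusted p = 0.236). Immediate early genes, which respond within minutes to stress and growth signals, rose by a median of 0.41 (13 of 14 higher, adjusted p = 5.83e-05; adjusted p = 0.451 with an estimated correlation). The list's median was 0.27 and 0.66 without B20 replicate 1 or vehicle replicate 1. Fosb stood at 1.80 ± 0.69 and Atf3 at 0.66 ± 0.22. Cell cycle genes had a median of -0.42 (adjusted p = 3.34e-14). The mitotic kinase Plk1 stood at -0.73 ± 0.32 and Tpx2, whose probes differed in sign, at -0.71 ± 0.30 (-0.34 with their mean).

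In energy metabolism, OXPHOS subunits rose by a median of 0.22 (64 of 76 higher, adjusted p = 4.11e-05) and hypoxia response genes by 0.15 (18 of 25 higher, adjusted p = 0.0153). Cytosolic ribosomal proteins rose by 0.26 (75 of 76 higher, adjusted p = 1.72e-12). With an estimated correlation adjusted p was 0.737, 0.625 and 0.625, and no member of the 3 lists passed. Muscle markers were higher in the same group. The highest OXPHOS scores, 6.08 and 5.83 in B20 replicates 2 and 1, came with muscle scores of -0.26 and 5.38. The OXPHOS call ended without B20 replicate 2 (adjusted p = 0.361), with normexp (0.0737), quantile normalisation (0.153), the authors' values (0.105) and array weights (0.0792). The hypoxia call ended without B20 replicates 1, 2 or 3 or vehicle replicate 2 (adjusted p = 0.0504, 0.22, 0.0855 and 0.372), with normexp (0.202) and with the slide as a block (0.0921), and its median was 0.29, 0.25 and 0.27 without B20 replicate 4 or vehicle replicates 1 or 3. The ribosomal call ended with quantile normalisation (0.126) and the authors' values (0.0649), and its median was 0.16 without vehicle replicate 1. Bnip3, a mitophagy receptor, differed by 1.02 ± 0.47, and glycolysis had a median of 0.18 (adjusted p = 0.0604).

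Adipocyte genes (16 of 16 higher, adjusted p = 1.42e-11) had 4 members that rose when adjusted over the list alone, with Adipoq at 3.01 ± 0.98 (1.95 without vehicle replicate 1). Skeletal muscle genes (18 of 18 higher, adjusted p = 5.99e-06) included the creatine kinase Ckm at 2.99 ± 1.69 (1.53 without B20 replicate 1). Erythroid genes had a median of 1.00 (6 of 6 higher, adjusted p = 0.00651; adjusted p = 0.578 with an estimated correlation). Without B20 replicate 1 the muscle call ended (median 0.78, adjusted p = 0.115), and without B20 replicates 1 or 2 the erythroid call did (adjusted p = 0.115 and 0.0938). The erythroid median was 1.55 without B20 replicate 4.

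Vegfa, the antibody's target, differed by 0.71 ± 0.47 (0.39 without vehicle replicate 2), Kdr, whose probes differed in sign, by 0.34 ± 0.27, Flt1 by -0.25 ± 0.44, and Pdgfrb by -0.11 ± 0.26. Slc2a1 differed by 0.18 ± 0.26, Hk2 by 0.77 ± 0.56 (1.18 within the slide of 8 arrays and -0.14 within the slide of 3), Ldha by 0.31 ± 0.18, Pdk1 by 0.17 ± 0.19 and Car9 by -0.15 ± 0.42 (adjusted p = 0.999 for each). Of the lists not called, macrophages had a median of 0.17, T and NK cells 0.27 and lipid synthesis 0.07 (exact permutation p = 0.0286, adjusted p = 0.236). Lymphatic endothelium (0.12) and basal epithelium (0.04) had positive medians and a negative direction in camera.

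Over all genes limma called 0 of 28074 (lowest adjusted p = 0.282), and 934 had an unadjusted p under 0.05, against 1404 by chance. The groups did not overlap for 5.38% of genes, against 5.71% by chance. Camera called 13 of 33 lists (9 higher, 4 lower), the estimated correlation 0 and fry 0. With the slide as a block the medians were 1.07 for the interferon response, -0.41 for the cell cycle, -0.45 for endothelium, -0.23 for angiogenic endothelium, -0.26 for fibroblasts and matrix and 0.86 for neutrophils. They were 0.41 for immediate early genes, 0.28 for ribosomal proteins, 0.21 for OXPHOS subunits, 0.11 for the hypoxia response, 2.13 for adipocytes, 1.96 for muscle and 0.95 for erythroid cells. Within the slide of 8 and the slide of 3 arrays, list means differed by 1.05 and 1.03 for the interferon response, -0.41 and -0.37 for the cell cycle, -0.31 and -0.93 for endothelium, and -0.25 and -0.47 for angiogenic endothelium. Differences were -0.01 and -1.04 for fibroblasts and matrix, 0.98 and 0.30 for neutrophils and 0.52 and 0.53 for immediate early genes. They differed by 0.36 and 0.14 for ribosomal proteins, 0.21 and 0.08 for OXPHOS subunits, 0.39 and -0.21 for the hypoxia response, 2.85 and -0.13 for adipocytes, 3.51 and -1.90 for muscle and 1.36 and -0.62 for erythroid cells.

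**Figure D2:**
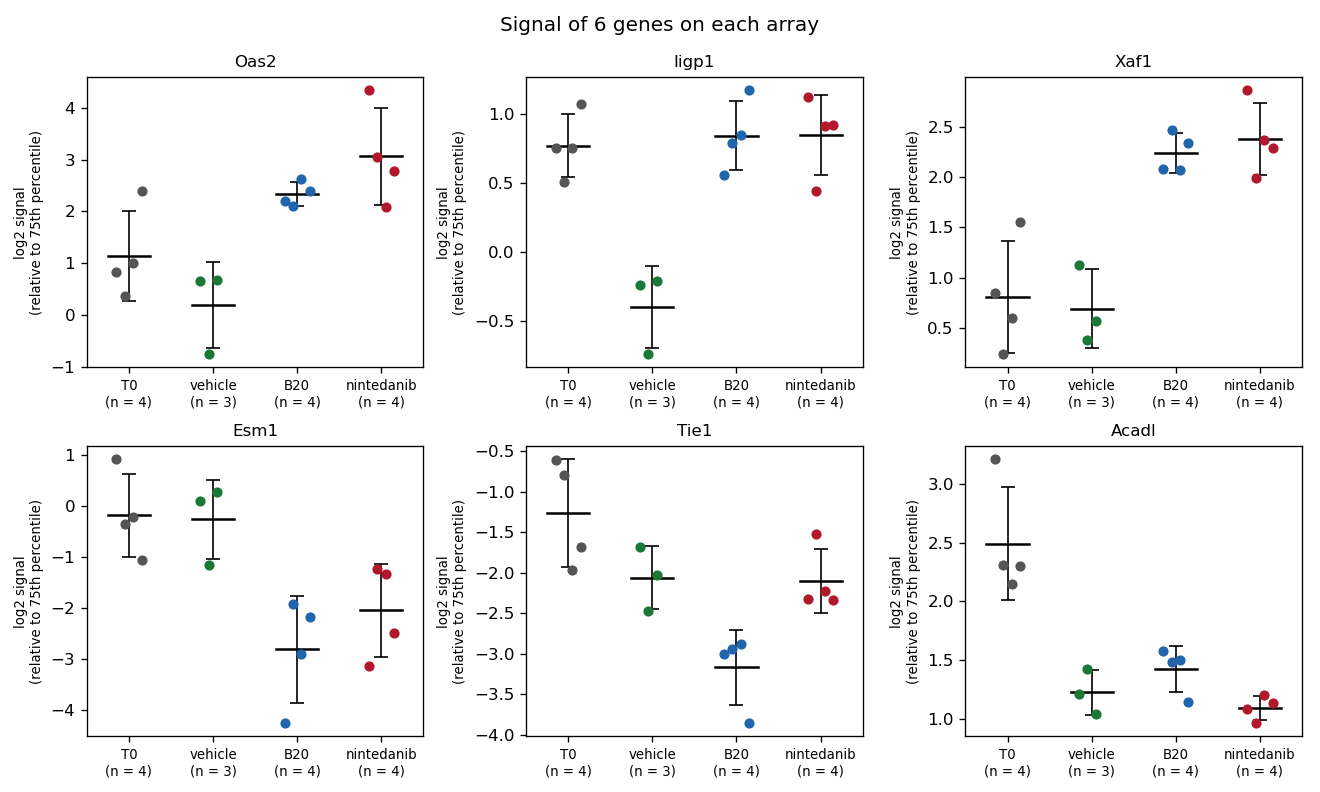
Log2 signal, relative to the 75th percentile of the array, of Oas2, Iigp1, Xaf1, Esm1, Tie1 and Acadl in T0, vehicle, B20 and nintedanib tumours, with 1 point per array, bars at the group mean and error bars of 1 SD. Esm1 averages -2.81 with B20 and -0.26 with vehicle, and Oas2 averages 3.07 with nintedanib and 0.19 with vehicle, with no overlap between the arrays of those groups.

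The direct comparison of nintedanib with B20 asked where the drugs differed. Camera called 12 lists, each with adjusted p = 0.869 with an estimated correlation. Endothelial genes were higher with nintedanib by a median of 0.35 (23 of 28 higher), interferon response genes by 0.23 (24 of 30 higher), angiogenic endothelium by 0.31 (10 of 14 higher), pericytes and smooth muscle by 0.36 (13 of 16 higher) and fibroblasts and matrix by 0.29 (14 of 21 higher). Cytosolic ribosomal proteins were lower with nintedanib by a median difference of -0.43 (76 of 76 lower), OXPHOS subunits by -0.33 (69 of 76 lower) and mitochondrial ribosome genes by -0.24 (63 of 74 lower). Fatty acid oxidation (-0.27, 17 of 20 lower), immediate early genes (-0.34, 12 of 14 lower), neutrophils (-0.35, 8 of 10 lower) and ER and amino acid stress (-0.19, 18 of 20 lower) were lower as well. Muscle markers stood lower with nintedanib by a median of -1.15 (18 of 18 lower, adjusted p = 0.0892) beside the OXPHOS and fatty acid oxidation genes, but the median was 0.16 without B20 replicate 1.

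Tie1 differed by 1.07 ± 0.34, Plvap, a component of vessel fenestrae, by 1.02 ± 0.32, Eng by 0.85 ± 0.29 and Pecam1, a junction protein of endothelium, by 0.52 ± 0.19. When adjusted over the list alone, the apelin receptor Aplnr rose (1.01 ± 0.26) and the chemokine receptor Cxcr4 fell by 0.68 ± 0.21, as did the neutrophil genes Il1b (-1.33 ± 0.39) and S100a8 (-1.23 ± 0.37). The collagen Col6a2 differed by 1.31 ± 0.39 (0.86 within the slide of 8 arrays and 2.66 within the slide of 3) and the pericyte gene Rgs5 by 0.82 ± 0.36. Of the lower lists, Mrpl33 of the mitochondrial ribosome differed by -0.61 ± 0.19 (-0.38 with quantile normalisation) and Atf3 by -0.61 ± 0.20. Genes of low p were Comp (1.89 ± 0.39) and Serpina3n (2.09 ± 0.46) among higher genes. Among lower genes they were Rnase10 (-1.11 ± 0.22) and Fgd3 (-0.94 ± 0.21). With normexp Tie1 and Pecam1 differed by 0.52 and 0.28. Kdr, whose probes differed in sign, stood at -0.55 ± 0.25 (-0.19 with their mean). None of these genes passed over all genes (adjusted p = 0.508 to 0.519).

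Camera called 12 of 33 lists (5 higher, 7 lower), with adjusted p = 1.25e-21 for ribosomal proteins, 3.79e-10 for OXPHOS subunits, 4.36e-05 for the mitochondrial ribosome, 3.48e-06 for endothelium, and 0.000531 for the interferon response. It was 0.0227 for immediate early genes, 0.0233 for fibroblasts and matrix, 0.0386 for ER and amino acid stress and for angiogenic endothelium, 0.0454 for fatty acid oxidation and for neutrophils and 0.0484 for pericytes and smooth muscle. The estimated correlation called 0, fry 0, and the exact permutation test gave no list a p under 0.05. Of the lists not called, glycolysis (-0.06), macrophages (-0.04) and erythroid cells (-0.16) had negative medians and a positive direction in camera. OXPHOS subunits and endothelium kept their call without any 1 array and under each scaling, and ribosomal proteins lost theirs with quantile normalisation (median -0.06, adjusted p = 0.0888). The interferon call ended without nintedanib replicate 1 (adjusted p = 0.134) and the mitochondrial ribosome call without B20 replicate 2 (0.4) and with normexp (0.327), with medians of -0.16 and -0.36 without nintedanib replicates 1 or 3. Immediate early genes lost theirs without B20 replicates 1 or 3 or nintedanib replicate 3 (0.174, 0.0775 and 0.463) and with normexp (0.201), with a median of -0.53 without B20 replicate 2. Fibroblasts and matrix lost theirs without B20 replicates 2 or 4 or nintedanib replicates 2, 3 or 4 (0.0555 to 0.193), with array weights (0.112) and on the slide with 8 arrays alone (0.891). Fatty acid oxidation lost its call without B20 replicates 1, 2 or 3, nintedanib replicates 1 or 3 or vehicle replicates 1 or 3 (0.0538 to 0.391), under each other scaling (0.0541 to 0.796) and with no filter or the stricter one (0.0819 and 0.0875). ER and amino acid stress lost its call without B20 replicates 1, 2 or 3 or nintedanib replicates 1 or 3 (0.0554 to 0.396), under each other scaling (0.0663 to 0.796), with no filter or the stricter one (0.0541 and 0.0702) and with array weights (0.0841). Neutrophils lost theirs without B20 replicates 2 or 3, nintedanib replicates 3 or 4 or vehicle replicates 1 or 3 (0.0588 to 0.488), with normexp (0.0537), the authors' values (0.134), no filter or the stricter one (0.0819 and 0.0702), array weights (0.131) and genes with a symbol (0.0524). The neutrophil median was -0.61 without nintedanib replicate 2. Angiogenic endothelium lost its call without B20 replicates 1 or 3, nintedanib replicates 2 or 3 or vehicle replicate 3 (0.0516 to 0.129), with the authors' values (0.178), genes with a symbol (0.0708) and on the slide with 8 arrays alone (0.105). Pericytes and smooth muscle lost theirs without B20 replicates 2 or 4, nintedanib replicates 2, 3 or 4 or vehicle replicates 1 or 3 (0.0594 to 0.251), with the authors' values (0.134), array weights (0.0841), genes with a symbol (0.0991) and on the slide with 8 arrays alone (0.444). Without B20 replicate 2 camera called 7 lists, and without nintedanib replicate 3 it called 6.

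Over all genes limma called 0 of 28074 (lowest adjusted p = 0.508), although 2695 had an unadjusted p under 0.05, 1094 higher and 1601 lower with nintedanib, against 1404 by chance. The groups did not overlap for 5.74% of genes, against 2.86% by chance. With only the arrays of the 2 groups, and without vehicle replicate 1, it called the same unnamed transcript (2.10, adjusted p = 0.0426 and 0.00384). Normexp moved the median of all genes to -0.16. With the slide as a block the medians of the called lists were as given above, except -0.18 for ER and amino acid stress. Within the slide of 8 and the slide of 3 arrays, list means differed by -0.49 and -0.25 for ribosomal proteins, -0.41 and 0.00 for OXPHOS subunits, -0.30 and 0.03 for the mitochondrial ribosome, -0.40 and 0.08 for fatty acid oxidation, 0.34 and 0.33 for the interferon response and -0.30 and 0.15 for ER and amino acid stress. They differed by -0.47 and -0.32 for immediate early genes, 0.30 and 0.54 for endothelium, 0.24 and 0.22 for angiogenic endothelium, 0.05 and 0.83 for pericytes and smooth muscle, 0.01 and 0.91 for fibroblasts and matrix and -0.35 and -1.18 for neutrophils.

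Across all 28074 genes the fold changes of the drugs against vehicle correlated at r = 0.532, with the same sign for 60.6% of genes. In 1000 simulations of unchanged groups against the same vehicle arrays the median r was 0.61 (61.7% of simulations at least as high) and the median share of the same sign 71.8%. The covariance was 0.0913, against a simulated median of 0.0818 (44.2% at least as high). Part or all of the correlation may come from the shared vehicle arrays, whose number of 3 does not leave 2 arrays on each side of a split.

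**Figure D3:**
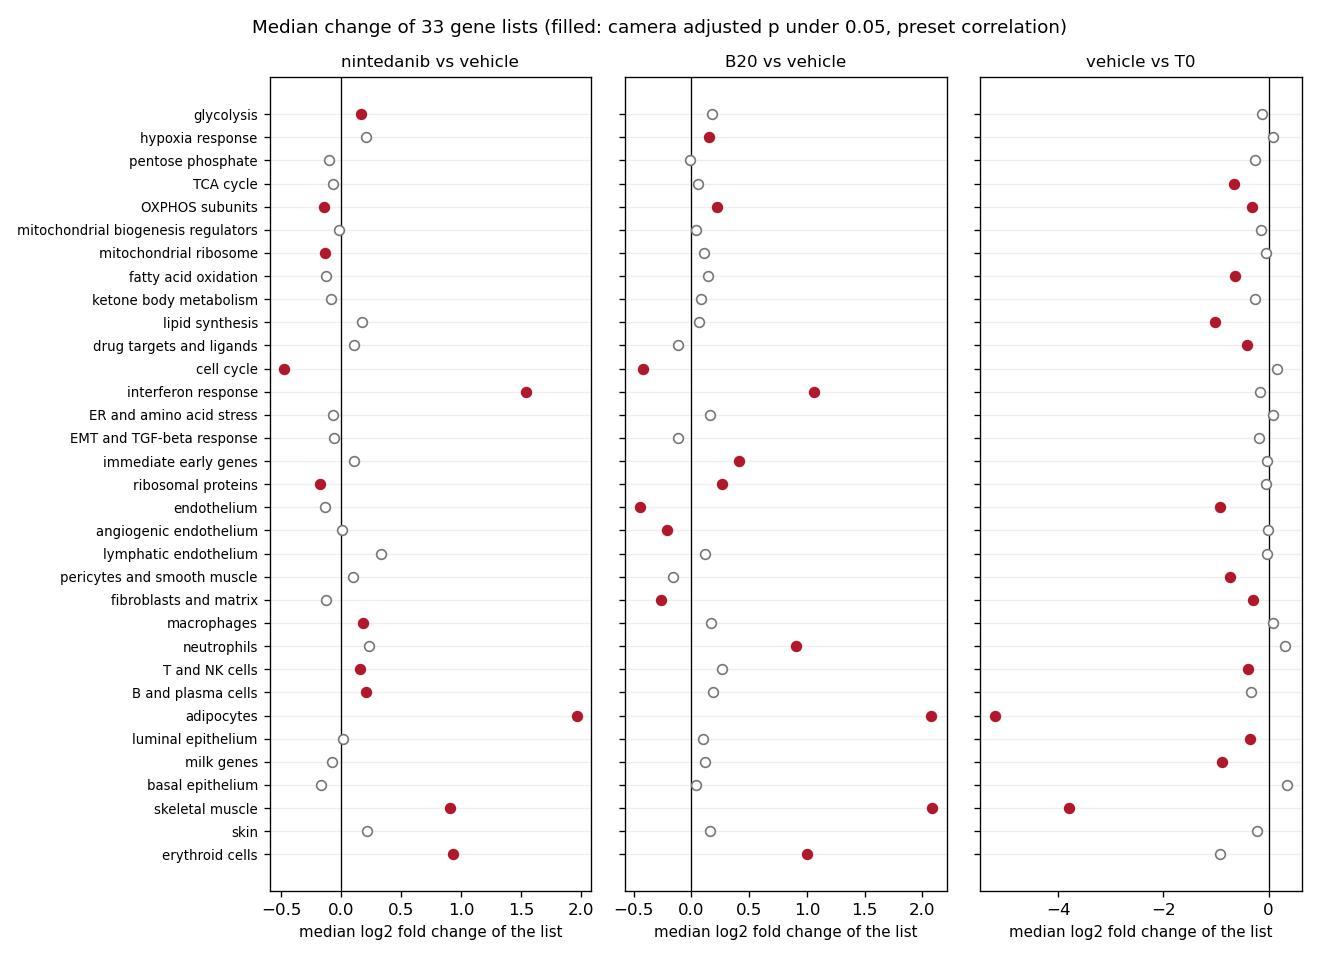
Median log2 fold change of the members of the 33 gene lists for nintedanib vs vehicle, B20 vs vehicle and vehicle vs T0, with filled points where camera called the list at its preset correlation (12, 13 and 13 lists). The interferon response lies at 1.54 and 1.06 for the drugs, and adipocytes at -5.20 for vehicle vs T0.

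The comparison of vehicle with T0 asked how the tumours changed over the period of treatment without a drug. Genes of fat tissue fell most: adipocyte markers went from a mean level of 4.14 ± 1.33 (SD, n = 4) at T0 to -0.85 ± 0.87 (SD, n = 3) with vehicle, a 31.7-fold difference, with 16 of 16 lower and 13 passing (adjusted p = 0.329 with an estimated correlation). Lipid synthesis genes fell by a median of 1.02 (16 of 19 lower, 7 passing), fatty acid oxidation by 0.65 (19 of 20 lower, 4 passing) and the TCA cycle by 0.66 (20 of 20 lower, 3 passing). For these 3 lists adjusted p was 0.329, 0.329 and 0.33 with an estimated correlation. Endothelial markers fell by 0.93 (27 of 28 lower, 5 passing) and milk genes by 0.88 (12 of 16 lower, 3 passing; adjusted p = 0.329 for both with an estimated correlation). Car9, a carbonic anhydrase induced by hypoxia, rose by 2.39 ± 0.42 (adjusted p = 0.00942; 0.0623 with only the arrays of the 2 groups), from -0.64 ± 0.55 (SD, n = 4) to 1.75 ± 0.42 (SD, n = 3).

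The largest falls were in genes of fat and of glucose storage: Gys2, a glycogen synthase (-7.31 ± 0.94, adjusted p = 0.00418), and Pck1, an enzyme of glucose and glycerol synthesis (-6.99 ± 1.07, adjusted p = 0.00611). They were followed by Adrb3, the adrenergic receptor of fat cells (-6.76 ± 1.03, adjusted p = 0.00611; -2.99 at its other probe), and Plin1, a coat protein of lipid droplets (-6.45 ± 1.00, adjusted p = 0.00653). The carboxylesterase Ces1f and the succinate receptor Sucnr1 were not well above background on any vehicle array and at least 113-fold and 79.4-fold lower than at T0 in the processed signal (adjusted p = 0.00584 and 0.00562). With normexp Gys2, Ces1f and Sucnr1 differed by -3.96, -3.26 and -2.44. In lipid synthesis, the desaturase Scd1 fell by 3.16 ± 0.42 (adjusted p = 0.0042) and Dgat2, which makes triglycerides, by 4.48 ± 0.80 (adjusted p = 0.00977). In fatty acid oxidation, Acsl1, which activates fatty acids, fell by 2.11 ± 0.33 (adjusted p = 0.00665) and the dehydrogenase Acadl by 1.27 ± 0.23 (1.22 ± 0.19, SD, n = 3, against 2.49 ± 0.48, SD, n = 4; adjusted p = 0.00977). These genes passed without any 1 array. With only the arrays of the 2 groups all genes named as passing for vehicle vs T0 lost their calls (adjusted p = 0.0528 to 0.206), except Dcpp1, Dcpp2 and Dcpp3. Acadl also lost its call with median scaling (0.0879).

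In the TCA cycle, pyruvate carboxylase Pcx fell by 1.79 ± 0.45 (adjusted p = 0.0376), the pyruvate dehydrogenase subunit Pdhb by 0.91 ± 0.23 (adjusted p = 0.0412) and malate dehydrogenase Mdh2 by 0.66 ± 0.18 (adjusted p = 0.0482). The Pcx call ended without T0 replicates 1 or 2 or vehicle replicates 1, 2 or 3, B20 replicates 1 or 3 or nintedanib replicates 2 or 3 (adjusted p = 0.050 to 0.123). The Pdhb call ended without T0 replicate 1, any 1 vehicle or B20 replicate or nintedanib replicates 2, 3 or 4 (0.0502 to 0.135). The Mdh2 call ended without any 1 of the 15 arrays but T0 replicate 3 (0.0505 without T0 replicate 4 to 0.151 without vehicle replicate 3). With the slide as a random block Pdhb and Mdh2 lost their calls (0.0731 and 0.0808), and with median scaling Pcx, Pdhb and Mdh2 did (0.0642, 0.233 and 0.406). Without a filter all 3 lost theirs (0.0569, 0.0659 and 0.0818), as did Pdhb with array weights (0.0546) and Mdh2 with normexp (0.0709), quantile normalisation (0.115), the authors' values (0.109) and the mean of its probes (0.0516). OXPHOS subunits fell by a median of 0.33 (76 of 76 lower, 0 passing with limma over all genes or the list alone; adjusted p = 0.571 with an estimated correlation), with Cox5a at -0.91 ± 0.28 (adjusted p = 0.0753). Adjusted over the list alone, 13 lipid synthesis, 10 fatty acid oxidation, 8 TCA cycle, 13 endothelium and 16 adipocyte genes fell. Markers of skeletal muscle, a tissue rich in TCA cycle, OXPHOS and fatty acid oxidation genes, were lower as well, with a median of -3.79 (18 of 18 lower, 0 passing, Myh4 at -4.17 ± 1.52, adjusted p = 0.13). For the muscle list adjusted p was 0.468 with an estimated correlation.

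Of the vascular genes, the adhesion gene Esam fell by 1.22 ± 0.29 (adjusted p = 0.0313), the tight junction gene Cldn5 by 1.71 ± 0.43 (adjusted p = 0.0386) and Cnn1, a protein of smooth muscle, by 2.91 ± 0.69 (adjusted p = 0.0311). All 3 calls ended without T0 replicates 1 or 2 or any 1 vehicle replicate, with adjusted p = 0.0557 to 0.12 for Esam, 0.069 to 0.132 for Cldn5 and 0.0678 to 0.0984 for Cnn1. Cldn5 also lost its call without nintedanib replicates 2 or 3 (0.0522 and 0.0502) and without a filter (0.0589). With the slide as a random block Esam, Cldn5 and Cnn1 lost their calls (0.0503, 0.0534 and 0.0514), and with median scaling Esam and Cldn5 did (0.146 and 0.118). Pericytes and smooth muscle fell by a median of 0.74 (15 of 16 lower, 1 passing, 3 adjusted over the list alone) and fibroblasts and matrix by 0.29 (14 of 21 lower, 0 passing), with adjusted p = 0.33 and 0.839 with an estimated correlation. Drug targets and ligands fell by a median of 0.40 (15 of 23 lower; adjusted p = 0.541 with an estimated correlation), with the FGF receptor Fgfr4 falling by 2.16 ± 0.46 (adjusted p = 0.0197; -1.27 with normexp and -0.37 at its other probe) and Pgf, a VEGF relative, rising by 1.63 ± 0.36 (adjusted p = 0.0229). Adjusted over the list alone 4 fell and 1 rose. The drug target list lost its call without T0 replicates 1 or 2 or vehicle replicate 2 (adjusted p = 0.194, 0.0746 and 0.234), and fibroblasts and matrix without the same arrays (0.194, 0.129 and 0.545), with the slide as a random block (0.0583), normexp (0.104), the authors' values (0.0528) and no filter (0.0742). With normexp and genes with a symbol the drug target list lost its call too (0.0567 and 0.0848). Fgfr4 lost its call without T0 replicate 1 or vehicle replicates 2 or 3 (0.058, 0.0759 and 0.0678), and Pgf without T0 replicates 1 or 2 or vehicle replicates 1 or 3 (0.0599, 0.0579, 0.0892 and 0.0759). Pdgfrb stood at -0.95 ± 0.26 (adjusted p = 0.052), Flt1 at -1.24 ± 0.44 (0.119), Kdr at -0.12 ± 0.27 (0.851) and Vegfa at -0.17 ± 0.47 (0.882).

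Among milk genes, the caseins Csn1s2a and Csn2 fell by 6.08 ± 1.06 (adjusted p = 0.00915) and 5.09 ± 1.18 (adjusted p = 0.0279). Csn2 lost its call without T0 replicates 1 or 2 or vehicle replicates 1 or 3 (0.0515, 0.0538, 0.0641 and 0.111) and with T0 replicates 1 and 2 as the only T0 arrays (0.0734). Luminal epithelium genes fell by a median of 0.35 (16 of 19 lower, 1 passing, 2 adjusted over the list alone; adjusted p = 0.329 with an estimated correlation), with the estrogen receptor Esr1 falling by 1.79 ± 0.39 (adjusted p = 0.0234). Esr1 lost its call without T0 replicates 1 or 2 or vehicle replicates 1, 2 or 3 (0.054 to 0.0901) and with the mean of its 3 probes (0.0746), which ranged from -1.79 to -0.23. T and NK cell genes fell by 0.39 (14 of 17 lower, 1 passing, 3 adjusted over the list alone; adjusted p = 0.329 with an estimated correlation), with Cd3g falling by 1.74 ± 0.39 (adjusted p = 0.0241; -1.16 with the authors' values). That call ended without T0 replicate 1 or vehicle replicates 1 or 3 (0.0598, 0.0878 and 0.0858) and with median scaling (0.0648). Of the hypoxia response, Angptl4, a lipase inhibitor also made by fat cells, fell by 2.12 ± 0.42 (adjusted p = 0.0152), a call that ended without vehicle replicates 1 or 3 (0.0639 and 0.0641). The list as a whole had a median of 0.09 (15 of 25 higher, adjusted p = 0.96). The largest rises were in the granzymes Gzme (at least 68.5-fold in the processed signal, adjusted p = 0.0118, its probe not well above background on any T0 array) and Gzmg (5.41 ± 1.08, adjusted p = 0.0156, well above background on 1 of 4). Next came Alkal2, a ligand of a receptor kinase (5.05 ± 0.95, adjusted p = 0.0118), and Dcpp1, Dcpp3 and Dcpp2 (5.08 ± 0.88, 4.99 ± 0.82 and 4.96 ± 0.58; adjusted p = 0.00889, 0.00758 and 0.00261), secreted proteins so alike in sequence that their probes may not tell them apart. Gzme and Gzmg lost their calls without vehicle replicate 1 (0.0507 and 0.0635), and Gzmg with normexp (0.0612) and the authors' values (0.0546). With normexp Gzme, Gzmg and Alkal2 differed by 2.75, 2.09 and 2.70.

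Glycolysis had a median of -0.13 (adjusted p = 0.299), with Hk2 at -1.52 ± 0.56 (adjusted p = 0.132), Slc2a1 at -0.18 ± 0.26 (0.754), Pdk1 at -0.20 ± 0.19 (0.597) and Ldha, whose probes differed in sign, at -0.15 ± 0.18 (0.7). Medians of other lists not called were -0.14 for mitochondrial biogenesis regulators (exact permutation p = 0.0286, adjusted p = 0.209), 0.16 for the cell cycle, -0.17 for the interferon response (adjusted p = 0.0811), -0.01 for angiogenic endothelium and -0.92 for erythroid cells. Macrophages had a median of 0.08 and a negative mean of -0.05 and direction in camera.

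Over all genes limma called 1440 of 28074 (848 higher, 592 lower; with normexp 454 and 484; 866 with a symbol, 400 higher and 466 lower), 1081 of them at least 2-fold, and the groups did not overlap for 16.9% of genes against 5.71% by chance. Without T0 replicates 1 or 2 or vehicle replicates 1, 2 or 3 it called 522, 702, 568, 524 and 470, and with only the arrays of the 2 groups 9. Without T0 replicates 3 and 4 it called 3369, in a fit chosen after seeing the data that keeps only the T0 arrays of slide 2. Scan day and T0 against end of treatment could not be told apart, and with the slide as a random block limma called 905. Camera called 13 of 33 lists, all lower, with adjusted p = 3.46e-21 for adipocytes, 2.34e-11 for endothelium, 4.44e-10 for OXPHOS subunits, 3.6e-08 for the TCA cycle and for fatty acid oxidation, 3.61e-08 for muscle, and 5.74e-08 for lipid synthesis. It was 0.000108 for milk genes, 0.000148 for pericytes and smooth muscle, 0.00103 for T and NK cells, 0.00429 for luminal epithelium, 0.0284 for drug targets and ligands and 0.0439 for fibroblasts and matrix. The estimated correlation called 0 and fry 2, adipocytes and lipid synthesis (adjusted p = 0.00481 and 0.0455), and the exact permutation test gave p = 0.0286 (adjusted p = 0.209) for adipocytes and for T and NK cells. Medians with the slide as a random block were -5.15 for adipocytes, -0.93 for endothelium, -0.33 for OXPHOS subunits, -0.66 for the TCA cycle, -0.66 for fatty acid oxidation, -1.02 for lipid synthesis, and -3.86 for muscle. They were -0.75 for pericytes and smooth muscle, -0.87 for milk genes, -0.37 for T and NK cells, -0.35 for luminal epithelium, -0.39 for drug targets and ligands and -0.26 for fibroblasts and matrix.

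The last comparisons asked how the drug-treated tumours differed from T0. Adipocyte markers fell by medians of 3.27 with nintedanib (13 of 16 passing) and 2.93 with B20 (12 passing), and endothelial markers by 1.11 (12 of 28 passing) and 1.48 (23 passing), with adjusted p = 0.354 and 0.33 for each list with an estimated correlation. Interferon response genes rose by 1.22 with nintedanib (14 of 30 passing) and 0.72 with B20 (9 passing), with adjusted p = 0.354 and 0.369 with an estimated correlation. T0 replicate 4 stood at a list mean of 1.51, among the B20 tumours (1.41 to 1.71), and the other T0 arrays between 0.17 and 0.61. Fatty acid oxidation fell by 0.89 and 0.57 (7 and 3 of 20 passing), the TCA cycle by 0.66 and 0.56 (8 and 5 of 20 passing), lipid synthesis by 1.26 and 0.98 (9 and 7 of 19 passing) and OXPHOS subunits by 0.48 and 0.12 (11 and 2 of 76 passing). With an estimated correlation adjusted p was 0.354 and 0.33 for fatty acid oxidation and lipid synthesis, 0.362 and 0.33 for the TCA cycle and 0.512 and 0.713 for OXPHOS subunits. Muscle markers stood at -2.86 and -1.57 on the same arrays. Cell cycle genes fell by 0.27 and 0.29, ribosomal proteins fell by 0.20 with nintedanib and rose by 0.22 with B20, and neutrophil and immediate early genes rose by 0.91 and 0.50 with B20. With an estimated correlation adjusted p was 0.737 and 0.681 for the cell cycle, 0.754 and 0.783 for ribosomal proteins, and 0.33 and 0.481 for neutrophils and immediate early genes.

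Limma called 3188 genes for nintedanib vs T0 (1919 higher, 1269 lower; with a symbol 926 and 924) and 2678 for B20 vs T0 (1652 higher, 1026 lower; with a symbol 723 and 803). With normexp the split for nintedanib vs T0 was 1133 higher and 1432 lower. The groups did not overlap for 17% and 15.6% of genes, against 2.86% by chance. For nintedanib vs T0 it called 1606, 1707 and 1925 without nintedanib replicate 1, T0 replicate 1 or T0 replicate 2, and 2046 with the slide as a random block. For B20 vs T0 it called 1208, 933, 1110 and 1398 without B20 replicate 2, B20 replicate 4, T0 replicate 1 or T0 replicate 2, and 1537 with the slide as a random block. Camera called 15 lists for nintedanib (1 higher, 14 lower) and 18 for B20 (4 higher, 14 lower), fry 9 each and the estimated correlation 0 each. Camera gave adjusted p = 4.55e-11 and 2.43e-06 for the interferon response, 3.77e-11 and 5.56e-12 for adipocytes, 4.55e-11 and 3.67e-21 for endothelium and 1.6e-13 and 0.00035 for OXPHOS subunits.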

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

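Dixon's ratio of the outlying array's gap to the range of its group was a planned test, and of the genes below only Cxcl9 and Ppp4r4 were chosen after their values were seen. The ratio was taken for list scores, signal measures and genes in the groups of 4 arrays, and it exceeded 0.829 in 13 of 378 groups. Chance alone gives about 1 in 20 groups, so these 13 are no more than chance would give, and none was weighed further.

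Among the list scores, nintedanib replicate 4 was low in neutrophil genes at -1.65, with the other 3 arrays between -0.51 and -0.31 (ratio 0.85). Nintedanib replicate 2 was high in milk genes at 3.79 against 2.45 to 2.56 (ratio 0.914), and B20 replicate 3 in skin genes at -1.46 against -2.36 to -2.22 (ratio 0.846).

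Of the vascular genes, Tie1 was low in B20 replicate 4 at -3.86 against -3 to -2.88 (ratio 0.878) and high in nintedanib replicate 2 at -1.52 against -2.34 to -2.23 (ratio 0.866). Flt1 was high in the same nintedanib array at 1.04 against 0.04 to 0.16 (ratio 0.88). Of the immune genes, Pou2af1 was high in nintedanib replicate 4 at -1.26 against -1.93 to -1.89 (ratio 0.94), Cxcl9 in nintedanib replicate 1 at -1.58 against -2.45 to -2.31 (ratio 0.839) and Gzmg in T0 replicate 3 at -4.94 against -7.48 to -7.07 (ratio 0.839).

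Acadl was high in T0 replicate 1 at 3.21 against 2.15 to 2.31 (ratio 0.849), Pcx in nintedanib replicate 4 at 3.70 against 2.95 to 3.03 (ratio 0.893) and Ppp4r4 in T0 replicate 1 at -4.44 against -4.85 to -4.79 (ratio 0.854). In the B20 group, Mcm2 was low in replicate 1 at 0.65 against 1.05 to 1.13 (ratio 0.833).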

How the results depend on the processing

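The tests with T0 replicates 1 and 2 as the only T0 arrays, on the 11 end-of-treatment arrays and on genes with a symbol were chosen after seeing the data, and all other settings were planned. Interferon response genes were called higher under 32 of 33 other settings with nintedanib (median 1.21 to 1.69) and 31 of 33 with B20 (0.75 to 1.31). Cell cycle genes with each drug (medians -0.56 to -0.39 and -0.48 to -0.32) and endothelium with B20 (-0.58 to -0.31) were called lower under 31 of 33. Adipocytes were called lower in vehicle than in T0 under 30 of 31 (-6.15 to -4.63). Where 31 of 33 called a list, the estimated correlation and fry, which drop the preset one, did not. OXPHOS subunits kept their sign for nintedanib vs vehicle (-0.25 to -0.05, called under 25 of 33), B20 vs vehicle (0.07 to 0.32, 26 of 33) and nintedanib vs B20 (-0.43 to -0.13, 31 of 33). Of list values under other settings, 996 of 1086 for B20 vs vehicle, 957 of 1086 for nintedanib vs B20, 983 of 1086 for nintedanib vs vehicle and 967 of 1020 for vehicle vs T0 kept their side of the threshold (959, 889, 946 and 928 with the sign of the median too). Of single gene values, 2185 of 2542 for vehicle vs T0 did, and no call turned. Among end-of-treatment groups there were 0 gene calls to lose. Lymphatic endothelium with B20 turned to a call higher on the slide with 8 arrays alone (0.501, adjusted p = 0.0374), and the cause was not tested.

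Genes called for vehicle vs T0 (1440 in all) numbered 938 with normexp (454 higher, 484 lower), 748 with median scaling (397 higher, 351 lower), 928 without a filter, 9 with only the arrays of the 2 groups, 5264 with array weights, 905 with the slide as a random block, 3369 with 2 T0 arrays and 2879 at an adjusted p under 0.10. For nintedanib vs T0 (3188) they numbered 1489 with median scaling, 1463 with only the arrays of the 2 groups, 7889 with array weights, 2046 with the slide as a random block, 5006 with 2 T0 arrays, 5371 at an adjusted p under 0.10 and 1882 at 2-fold. For B20 vs T0 (2678) they numbered 1573 with normexp (865 higher, 708 lower), 1279 with median scaling, 983 with only the arrays of the 2 groups, 6047 with array weights, 1537 with the slide as a random block, 4290 with 2 T0 arrays, 1731 with a symbol only, 4601 at an adjusted p under 0.10 and 1691 at 2-fold. The lower counts with fewer arrays or a 2-fold minimum, and the higher ones at 0.10, follow from how those settings are made, as do fewer calls where fewer genes were tested. For the others the cause was not tested. Array weights called 2 genes for nintedanib vs vehicle, and only the arrays of the 2 groups gave 1 for nintedanib vs B20.

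With 1 array left out the genes called ranged from 0 to 1 for nintedanib vs vehicle and for nintedanib vs B20, 470 to 2116 for vehicle vs T0, 1606 to 4023 for nintedanib vs T0 and 933 to 3252 for B20 vs T0, and the lists called from 7 to 16 for nintedanib vs vehicle and 6 to 13 for nintedanib vs B20. Camera with an estimated correlation called 0 lists in each of the 6 comparisons, where 1, 2, 0, 3, 0 and 2 lists had an unadjusted p under 0.05 in the order of the report. Fry called 1 for nintedanib vs vehicle, 0 for B20 vs vehicle and for nintedanib vs B20, 2 for vehicle vs T0 and 9 each against T0. Quantile normalisation left 6 lists for nintedanib vs B20. The median of all genes for vehicle and B20 against T0 moved to 0.12 and 0.11 with array weights, to 0.12 and 0.14 without T0 replicate 3 and to 0.16 and 0.17 with 2 T0 arrays (0.12 for nintedanib), and to 0.11 for B20 vs T0 without B20 replicate 3.

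With the replicate block, which takes the replicate number as a pairing, limma called 0 genes in the 3 comparisons among end-of-treatment groups, 1238 for vehicle vs T0, 2606 for nintedanib vs T0 and 2051 for B20 vs T0, and camera called 10, 14, 10, 12, 15 and 18 lists in the order of the report. The numbers do not pair the samples: deviations of same-numbered arrays correlated at -0.246 to 0.38, in no comparison was every pair over 0.1, and in none did every array correlate best with its own number. Under the block macrophages, T and NK cells, and B and plasma cells lost their calls for nintedanib vs vehicle (adjusted p = 0.0795, 0.0798 and 0.0714), as did fatty acid oxidation, pericytes and smooth muscle, and neutrophils for nintedanib vs B20 (0.0561, 0.0597 and 0.0591). For vehicle vs T0 fibroblasts and matrix (0.0516), Pcx (0.0662), Pdhb (0.0725), Mdh2 (0.0794), Esam (0.0508), Cnn1 (0.0523) and Zeb2 (0.0686) did.

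Normexp on the mean raw signal was not run, since that column is not among those used here, and the median raw signal took its place. Signal over background limits dim genes, whose fold changes depend on the background correction, and genes not well above background in 1 group have only a bound. The 3 vehicle arrays limit the precision of each comparison with vehicle.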

Other observations

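The splits of the samples were planned, and the tests of cell content, slide, fat, muscle and the label of T0 replicate 4, as well as the 4 genes of the next paragraph, were chosen only after the values had been seen.

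Immune and matrix genes outside the rule for named genes also differed between vehicle and T0. The monocyte chemokine receptor Ccr2 fell by 1.68 ± 0.32 (adjusted p = 0.0129), from 0.21 ± 0.16 (SD, n = 4) to -1.47 ± 0.73 (SD, n = 3), and kept its call under 28 of 29 other settings (adjusted p = 0.0973 with only the arrays of the 2 groups). Cxcl9, a chemokine induced by interferon gamma, fell by 1.87 ± 0.39 (adjusted p = 0.0187), a call that held under 20 of 29 settings and ended without T0 replicates 1 or 2 or vehicle replicates 1, 2 or 3 (adjusted p = 0.05, 0.0505, 0.0548, 0.0604 and 0.0647), with quantile normalisation (0.0717), median scaling (0.06), the authors' values (-0.92, 0.0654) and, as for Tnc and Zeb2, with only the arrays of the 2 groups (0.114). Of the 20 members of the EMT and TGF-beta response, 4 rose and 6 fell when adjusted over the list alone, and the list was not called (median -0.18, camera adjusted p = 0.235). The matrix glycoprotein Tnc rose by 2.27 ± 0.53 (adjusted p = 0.0291), while the transcription factor Zeb2 fell by 1.15 ± 0.28 (adjusted p = 0.0338). The Tnc call ended without T0 replicates 1 or 2 or vehicle replicates 1 or 3 (0.0844, 0.0675, 0.0916 and 0.116), with normexp (1.04, 0.0627) and with the mean of its probes (0.0909). The Zeb2 call ended without the same T0 arrays or any 1 of the vehicle arrays (0.0561 to 0.121), with median scaling (0.166), without a filter (0.0532) and with the slide as a random block (0.0536).

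Each comparison was refitted on the 35 splits of its arrays into groups of the same sizes. Against T0, only 1 split, the real one, gave as many genes: 1440 for vehicle (highest other split 1251), 3188 for nintedanib (100) and 2678 for B20 (116). Each count alone thus had a share under 0.05. But 1 of 35 is the smallest share possible and was not adjusted over the 6 comparisons, so chance is not excluded. The split of 1251 was the real one with T0 replicate 4 moved to vehicle, which groups of 4 and 4 do not allow. Among end-of-treatment groups limma called 0 genes in the real split, with 2, 0 and 1 in the highest other split, in the order of the report. Any of the 35 splits gives at least 0, so the count of 35 in each is fixed and says nothing about chance. For the number of lists called, chance cannot be excluded in any comparison: 8, 14, 15, 22, 14 and 7 of the 35 splits gave as many as the real 12, 13, 12, 13, 15 and 18 lists, in the order of the report, with 20, 18, 19, 20, 19 and 22 in the highest other split.

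Interferon response genes stood 1.21 higher in the 8 drug-treated tumours than in the 3 vehicle tumours. With the macrophage and the T and NK cell scores as covariates the difference was 1.38 ± 0.22 (SE), which argues against more of these cells as the whole cause. Within the slides of 8 and of 3 arrays the list means differed by 1.39 and 1.35 with nintedanib and 1.05 and 1.03 with B20, which argues against the slides, while the slide as a block (1.21 ± 0.23) could move little, since both slides hold all 3 groups in like shares. T0 replicates 1 to 3 (0.17 to 0.61) lay like vehicle (0.15 to 0.85), with both drugs above T0 (14 and 9 of 30 passing). This argues against a low vehicle level for the list mean. But T0 replicate 4 stood at 1.51, T0 was scanned on another day, and T0 overlapped the drugs, not vehicle, in Iigp1 and Gbp2b. A response to both drugs may explain the rise, as a hypothesis found and tested on the same arrays. Chance stays open, since the permutation p of 0.0286 for each drug did not survive adjustment over the lists (0.471 and 0.236).

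Fatty acid oxidation, TCA cycle and lipid synthesis genes stood lower in vehicle than in T0 by -0.85, -0.63 and -1.31 in their mean scores. With the adipocyte score as a covariate over the 15 arrays the differences were 0.16 ± 0.35, 0.01 ± 0.35 and 0.01 ± 0.43 (SE), and within groups the lists followed the adipocyte score (slopes 0.202 ± 0.060, 0.127 ± 0.060 and 0.265 ± 0.074). With the skeletal muscle score the first 2 differences were -0.56 ± 0.27 and -0.48 ± 0.24, only just over 2 SE, which argues weakly against muscle as the whole cause. More fat tissue in the T0 samples is a candidate explanation for all 3 lists. A fall within the tumour cells stays open, since these are whole tissue samples and the adipocyte score itself differs between the groups.

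T0 replicate 4, which carries the vehicle label beside its T0 title, lay at 0.48 between the vehicle mean (0) and the T0 mean (1) over the 2116 genes called without it, and nearer T0 for 50.8% of them. The other T0 arrays, left out in the same way, lay at 1.19, 1.03 and 0.60 (94.4%, 88.7% and 61.3% nearer T0) and the vehicle arrays at 0.02, 0.16 and 0.21 (14% to 16%). Of the 14 lists whose scores separate the other T0 arrays from vehicle (chance separates 10%), it lay within the T0 range for 6, such as milk genes (4.82, T0 3.86 to 5.51, vehicle 2.54 to 3.33). It lay within the vehicle range for 3, such as pericytes and smooth muscle (-0.43, T0 -0.01 to 1.33, vehicle -1.04 to -0.23). For 4 it lay between, such as adipocytes (2.87, T0 3.16 to 5.59, vehicle -1.79 to -0.09), and for erythroid cells beyond vehicle. Dcpp1 (-0.20; T0 -1.45 to -1.14, vehicle 3.49 to 4.81), Gzme (-6.66; vehicle -1.87 to 2.12) and Csn1s2a (7.04; vehicle -0.77 to 1.95), lay near T0, but were named with this array in T0, which fixes part of that, and Car9 (0.16) lay between -0.77 and 1.35. The 6 lists argue against a vehicle sample like the other 3, but the 3 lists and the split of the 2116 genes leave the label open: the 2 cannot be told apart, its slide and scan day are those of T0, and no biological explanation was tested.

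T0 replicate 3 had more probes well above background than any other array. Of 1399 probes for olfactory and vomeronasal receptors, which mammary tissue is not known to express, 64.0% were well above background, against 8.43% to 22.0% on the other 14 arrays.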
